A study of Drosophila melanogaster with 4 samples.

How the data were processed

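ChIP-seq of a Dll protein fused to enhanced GFP was made from whole Drosophila melanogaster embryos in 4 biological replicates, which are 1 group. Per the labels, chromatin was sonicated and precipitated with an antibody against GFP. Per the sample descriptions deposited with the lists, each replicate's own peaks derive from that sample's alignments and 1 further file, and the series-level lists derive from the alignments of all 4 samples and 1 further file. The aligner, the peak caller and their versions are not given in the sources used here, and the control library behind the peak calls was not analysed here.

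The peaks were placed by the authors on the dm6 build. The signal in each list is the authors' deposited peak height as their caller gave it, and its normalization is not given in the sources used here. The score is the authors' deposited scaled IDR (irreproducible discovery rate), at most 1000, equal in the ranked lists to 125 times minus log2 of the global IDR. The deposited −log10 columns hold the authors' −log10 of the q value and, in ranked lists, of the global IDR. Every deposited thresholded list already stops at a score of 830, a global IDR of 0.01. The planned stricter threshold therefore used its stated fallback, the upper 50% of peaks by signal.

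In all, 22 peak lists were used: a ranked and a thresholded list for each of the 4 replicates, and 7 ranked and 7 thresholded series-level lists. All conservative peaks were found in 1 of the ranked series-level lists. Another 14 signal columns of the ranked series-level lists hold values per replicate with no sample name and were not used. Coordinates were compared with the Drosophila release 6 reference, and every peak ended within its chromosome. Genes came from Ensembl release 115 (BDGP6.54), with 13968 protein-coding genes on arms 2L, 2R, 3L, 3R, 4, X and Y. Peaks on other scaffolds and the mitochondrial genome were left out of the tests.

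Each deposited row was counted as a peak, including the 421 rows of the conservative list that repeat an interval with another summit. Overlap meant at least 1 bp, counted in Python and checked with bedtools 2.31.1, and was set against 100 circular shifts of the lists. Signal ranks were compared with Spearman's rho. Summits were placed, in this order of priority, in promoters (500 bp upstream to 100 bp downstream of a TSS), 5' UTRs, coding sequence, 3' UTRs, other exons, introns and intergenic DNA, and set against 1000 circular shifts (100 for each own list). The 17 gene lists were tested by the number of genes that own a summit, against 10000 random lists matched on decile of territory, the stretch of the arm nearest to a gene's TSS. The 23 motifs were counted on both strands within 50 bp of each summit and in the flank 400 bp to the left, with the exact McNemar test. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each family, and the threshold was 0.05.

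The lists and motifs were fixed before the data were examined. The gene lists covered appendage patterning, Hox and head selectors, segmentation, the Wnt, Dpp, Notch, EGFR and Hedgehog pathways, proneural and sensory organ, neural, mesoderm, endoderm and fat body, tracheal and salivary, epidermis and cuticle and germline markers, ribosomal proteins and the proteasome. Older symbols were matched for 7 entries, and 3 entries matched no single gene and were left out. The genes named in the text were also chosen by a fixed rule: Dll, the first 25 genes owning the strongest conservative peaks seen in at least 3 replicates, up to 4 members of each list that passed and at most 2 of each list that did not, by the signal of their strongest peak.

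Peak lists hold no read counts, so depth per sample is unknown and no interval that needs it is given. Precision comes from the spread over the 4 replicates, while the p-values measure only the spread between peaks, genes or shifts. The signal was ranked within each list and never compared between lists. The alternatives were the stricter peak set, the 6 other thresholded series-level lists, peaks seen in at least 2 or in all 4 own lists, each replicate left out in turn, other overlap rules, another promoter, other backgrounds, other rules of ownership and matching, and other motif windows and controls. Keeping 1 summit per merged region was added after the data were seen, as were the signal bins, the position relative to the TSS, the map of Dll and the count near tRNA genes. Scripts used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. On simulated data, the promoter test recovered 33.1% where 33.9% was planted over 2000 summits, and the motif test recovered 9.75% where 9.65% was planted over 2000 summits. Of 50 lists of 25 genes with bound genes drawn 2 times as often or more, 96.0% passed a raw p of 0.05, against 5% of 200 lists with none planted. Smaller excesses and adjusted p were not simulated, so the 96.0% is not the power of the list test for them.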

Results

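Binding of the homeodomain transcription factor Distal-less (Dll), which specifies legs, antennae and other ventral appendages of the fly, was profiled by ChIP-seq in whole Drosophila melanogaster embryos aged 0 to 24 h. The flies carried a Dll protein fused to enhanced GFP, and chromatin sheared to 200 to 800 bp was immunoprecipitated with an antibody against GFP. All 4 samples belong to 1 group and are biological replicates by their labels. No second condition was part of the design, so the comparisons are between replicates and between bound regions and the rest of the genome. Each replicate has its own list of peaks. A list named conservative by the submitters derives, per the sample descriptions, from the alignments of all 4 replicates, and which replicates set its threshold is not stated there. Among the thresholded series-level lists, only this list and that of 6226 peaks held mitochondrial peaks. Among the own lists only those of replicates 1 and 2 did, so the conservative threshold may rest on these 2 replicates. The lists give no read counts, so the depth of each sample is unknown.

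The first question was whether the 4 replicates found the same regions. The replicates' own lists held 3157 ± 543 peaks on the nuclear chromosomes (mean ± SD, n = 4), from 2523 in replicate 3 to 3610 in replicate 2. On average 81.2% ± 7.61 (SD, n = 4 replicates) of a replicate's peaks overlapped a peak of another replicate by at least 1 bp. When the lists were shifted along their chromosome arms, the mean overlap over the 12 ordered pairs was 1.65%. The highest share was 91.5%, for peaks of replicate 3 seen in replicate 2, and the lowest was 67.3%, for peaks of replicate 2 seen in replicate 3.

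The conservative list held 5203 nuclear peaks, which formed 3977 separate regions. Of these peaks, 2480 (47.7%) overlapped a peak in every replicate's own list and 866 (16.6%) overlapped none. The own lists of replicates 1 and 2 overlapped 70.8% and 72.7% of them, and the shorter lists of replicates 3 and 4 overlapped 55.7% and 60.7%. Whether this difference comes from list length or from the replicates that set the conservative threshold was not tested. The signal of overlapping peaks was correlated across peaks, with a mean Spearman rho of 0.665 ± 0.0351 (SD over 6 pairs), from 0.624 for replicates 1 and 3 to 0.723 for replicates 3 and 4. For this, each row of one list, weaker summits of a shared interval included, was paired with the highest signal among the rows it overlapped in the other list. Peaks are not independent replicates, and no p-value was computed for these correlations. With 1 summit kept per merged region, mean rho was 0.922, and with a reciprocal overlap of 50% the share of conservative peaks seen in every replicate was 21.7%.

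The second question was where in the genome the peaks lie. Promoters, taken from 500 bp upstream to 100 bp downstream of the TSS of a protein-coding gene, held 3900 of the 5203 conservative summits (74.96%), against 7.10% ± 0.484 (SD over 1000 shifts) when the summits were shifted along the arms. This was a 10.6-fold excess in the conservative list and an 11.9-fold ± 0.251 excess (SD, n = 4) in the replicates' own lists. Summits in 5' UTRs were 2.69-fold more frequent than in the shifts, and 1.66-fold ± 0.224 in the own lists (SD, n = 4). Introns, with 9.76% of summits against 40.8%, intergenic DNA, with 4.79% against 28.0%, coding sequence, with 3.63% against 16.0%, and 3' UTRs, with 0.577% against 4.59%, were all under-represented.

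Each of these 6 classes had an adjusted p of 0.00233 in the two-sided permutation test by circular shifts, with a raw p of 0.001998, the smallest that 1000 shifts can give. Other exons held 1.29% of summits against 1.63% in the shifts and did not pass, with an adjusted permutation p of 0.116 (0.512-fold ± 0.185 in the own lists, SD, n = 4), but they passed as under-represented in 9 of the alternatives. The replicates ranged from 82.0% to 85.7% of summits in promoters. Against random draws from the ranked candidate peaks of the same set the promoter excess was 4.69-fold, and with a promoter of 1000 bp on each side of the TSS it was 4.34-fold, while the 5' UTR value turned to 0.504-fold. Among the upper 50% of peaks by signal, the 5' UTR excess ended, at 1.05-fold (adjusted permutation p = 0.767).

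**Figure D1:**
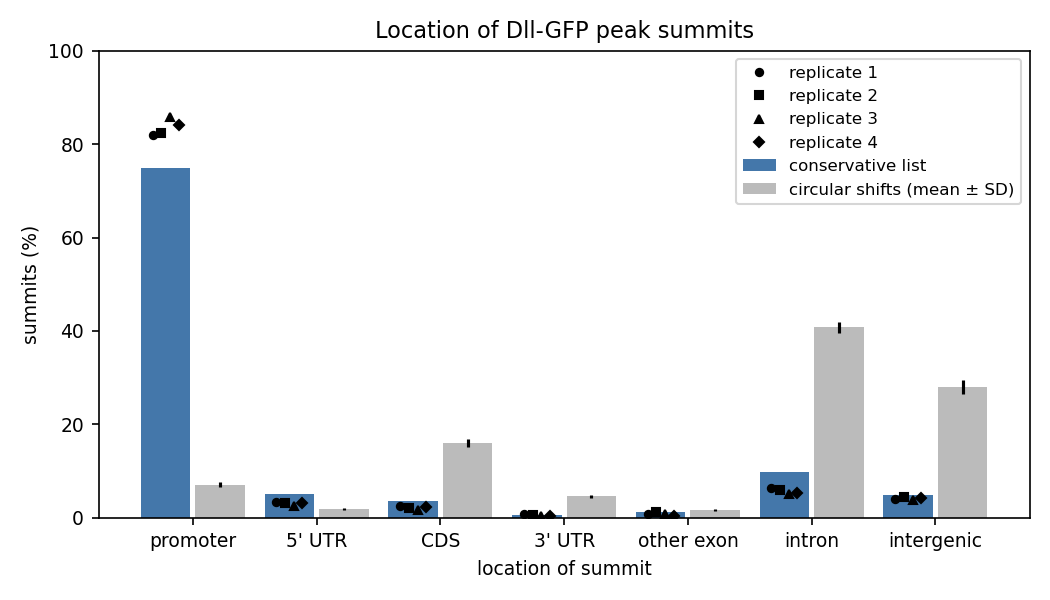
Share of peak summits (%) in each genomic class for the conservative list (blue bars), for 1000 circular shifts of it (grey bars, mean ± SD) and for each replicate's own list (black symbols). Promoter shares of the 4 replicates sit between 82.0% and 85.7%, above the shifted mean of 7.10%.

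Most summits lay close to a TSS. The median distance from a conservative summit to the nearest TSS was 107 bp, and in the own lists the median was 83 ± 2.94 bp (SD, n = 4). Among the 4402 summits within 500 bp of a TSS on a single strand, 63.6% were upstream of it, with a median position of -34 bp. A summit was owned by 3872 of 13968 protein-coding genes (27.7%), where the owner is the gene with the nearest TSS. Only 605 summits (11.6%) lay over 1000 bp from any TSS. Here and below, TSS means that of a protein-coding gene, so these summits may lie near other genes. Of the 605, 56 lay within 500 bp of a tRNA gene. In all, 107 of the 605 (17.7%) were seen in every replicate, against 51.6% of the 4598 nearer summits. By arm, the density of conservative peaks was 44.4 per Mb on 2R, 39.0 on 2L, 39.0 on X, 37.3 on 3R, 36.2 on 3L and 26.0 on chromosome 4. In the own lists the densities of chromosome 4, at 16.1 ± 3.60 per Mb, and 2R, at 26.4 ± 5.04 per Mb (SD, n = 4), differed by more than the spread of either, and no peak of these lists lay on Y.

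Strong peaks were nearly all at promoters, and weaker peaks were more dispersed. Each list was split by signal into 5 bins of equal size. In bin 1 of the own lists, with the highest signal, 96.1% ± 0.580 of summits were in promoters, against 67.2% ± 2.00 in bin 5, with the lowest (SD, n = 4). In the conservative list, 98.7% of peaks in bin 1 were seen in every replicate, against 11.8% in bin 4 and 26.9% in bin 5. Overlap was counted by interval, so a weak summit of a shared interval counts as seen wherever that interval was. The higher value in bin 5 than in bin 4 therefore does not show that its summits were better reproduced. The share of summits over 1000 bp from a TSS was 2.33% ± 0.222 in bin 1 of the own lists, highest in bin 4 at 14.3% ± 1.76, and 10.8% ± 1.97 in bin 5 (SD, n = 4). The signal is the authors' own value for each peak and was used only to rank peaks within a list.

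**Figure D2:**
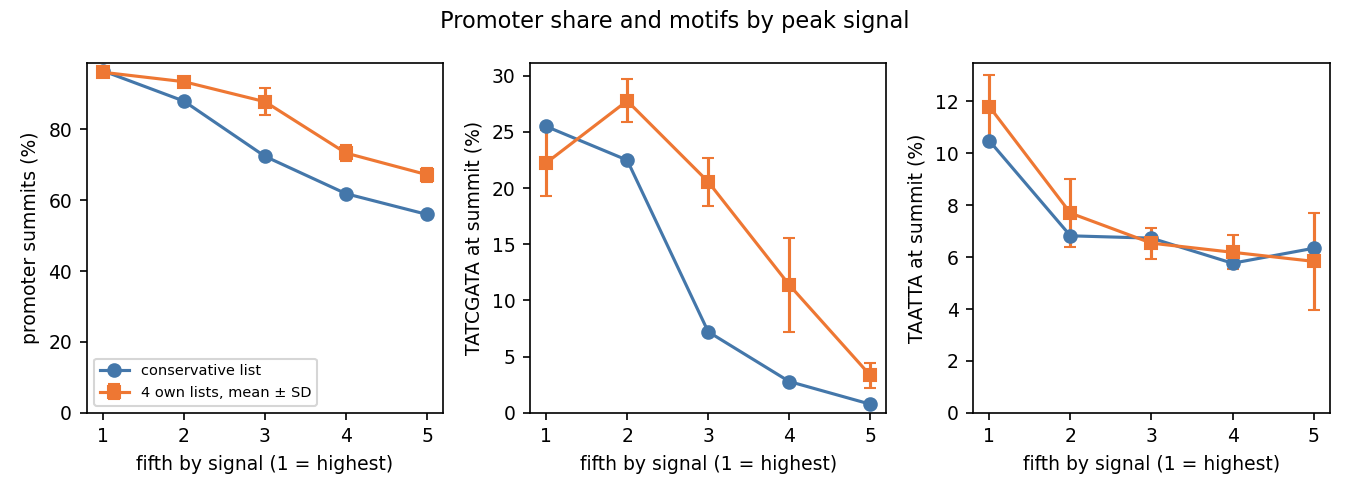
Share of summits (%) in promoters, with TATCGATA and with TAATTA within 50 bp, by bin of peak signal (1 is the highest), for the conservative list (circles) and the 4 own lists (squares, mean ± SD). Promoter share in the own lists went from 96.1% in bin 1 to 67.2% in bin 5.

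The 25 genes owning the strongest conservative peaks that were seen in at least 3 replicates were reached with 23 peaks. All 23 peaks were at promoters and in all 4 own lists, where each lay within the top 1.27% of peaks in every replicate. The strongest of all was at the promoter of mtSSB, which encodes the mitochondrial single-stranded DNA binding protein, on dm6 chromosome 3R from 16204809 to 16205581, with its summit 52 bp from the TSS. It had the highest signal of all nuclear peaks in 4 of 4 own lists, a mean rank of the top 0.0324% ± 0.00582 of each list (SD, n = 4). As its rank was the same in each list, this SD reflects only the length of the lists.

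Among these genes, Rpn6, a lid subunit of the proteasome (2R from 14752005 to 14752777), ranked in the top 0.115% ± 0.0426 of the own lists. RpL32, a protein of the large ribosomal subunit (3R from 30045940 to 30046702), ranked in the top 0.281% ± 0.184. MED7, a Mediator subunit (3R from 10760787 to 10761400), ranked in the top 0.468% ± 0.224, and Pp2A-29B, the scaffold subunit of protein phosphatase 2A (2L from 8365465 to 8366556), in the top 0.744% ± 0.227 (all SD, n = 4). RhoGAP93B (3R from 21097537 to 21098230), with the next strongest conservative peak after that of mtSSB, ranked in the top 0.0649% ± 0.0116 (SD, n = 4). It came next after mtSSB in each own list, so this SD too reflects only list length. Also in this group were MESK2, CG14441, Mic26-27, Gp150, Jwa, CG1965, PGAP3, Oatp30B, CG11857, Mppe, Dpit47, Hacl, CG8613, Epg5 and XNP, the fly relative of the chromatin remodeller ATRX. CG8043 and CG11755 shared 1 promoter peak, as did Sry-alpha and Sry-beta.

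The Dll gene itself (2R from 24814822 to 24835667, + strand) owned 2 conservative peaks. One lay at its promoter from 24814432 to 24815027, with the summit 92 bp from the TSS, and was seen in all 4 own lists, where it ranked on average at 64.4% ± 8.37 from the top (SD, n = 4). The other lay in an intron from 24829552 to 24830147, 15028 bp from the TSS, and was in none of the own lists. By signal, the promoter peak lay in the lower part of each own list.

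**Figure D3:**
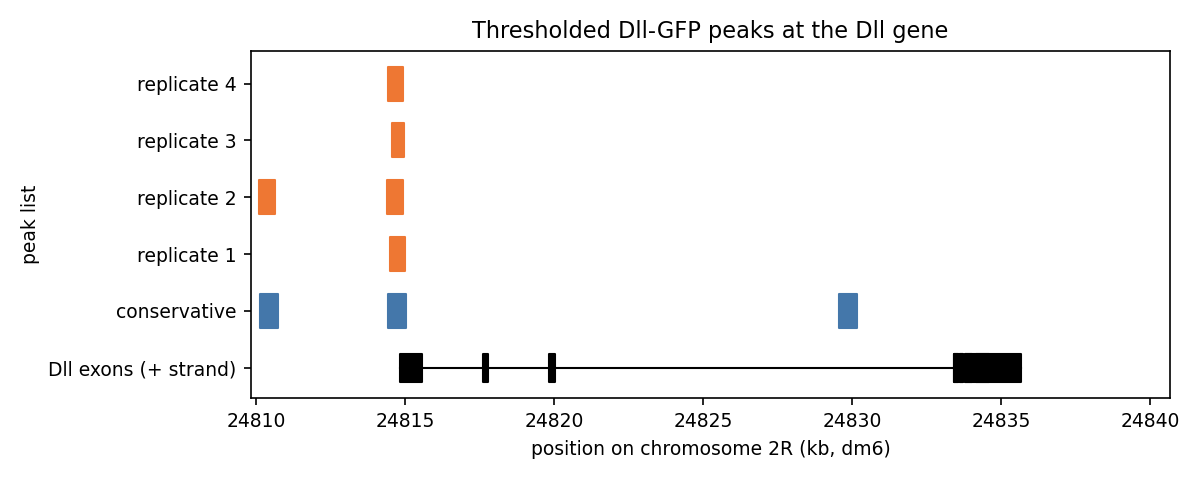
Map of the Dll gene on dm6 chromosome 2R (kb), with exons (black), conservative peaks (blue) and each replicate's own peaks (orange), drawn to scale. The promoter peak is in all 4 own lists, the intronic peak in none, and the peak upstream, starting at 24810128, overlaps a peak of replicate 2.

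The next question was which developmental and cellular gene groups own the summits. Genes of appendage patterning owned a summit more often than random genes with a territory of similar length: 18 of 33 did, 1.92 times the matched mean of 9.35, and the ratio was above 1 in 4 of 4 replicates (1.71 ± 0.341, SD, n = 4). Wnt pathway genes did so for 13 of 23, a ratio of 2.01 (2.15 ± 0.245 in the replicates). Ribosomal protein genes did so for 38 of 88, a ratio of 1.58 (1.97 ± 0.171), and proteasome genes for 23 of 48, a ratio of 1.78 (1.95 ± 0.146). These 4 of the 17 lists passed the two-sided permutation test over 10000 matched lists, with adjusted permutation p of 0.0215 for the appendage, ribosomal and proteasome lists and 0.0374 for the Wnt list. The random genes were drawn singly, without regard to position. In the appendage list drm, sob and odd lie close together on 2L, lbl, lbe and C15 on 3R, and bab1 and bab2 on 3L. All of these own a summit, and the p-value takes no account of such clusters.

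All 4 calls ended when random genes were matched also on having a ranked candidate peak at the promoter, with ratios of 1.26 for the appendage, 1.39 for the Wnt, 1.19 for the ribosomal and 1.57 for the proteasome list and adjusted permutation p from 0.0816 to 0.662. The ranked candidates include every conservative peak, so this matching is made in part on the tested peaks themselves. The appendage and Wnt calls also ended when only peaks seen in at least 2 of the 4 own lists were kept, with ratios of 1.89 and 2.03 and an adjusted permutation p of 0.130 for each. Both calls ended among the upper 50% of peaks by signal, where the ratios were 2.13 and 1.89 and the adjusted permutation p 0.150 and 0.387. The same held when a gene was given every summit in its body or 2000 bp upstream, with ratios of 1.06 and 1.34 and adjusted permutation p of 0.942 and 0.6004.

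Within the appendage list, the strongest peak was at the promoter of sob, an odd-skipped family zinc finger gene (2L from 3580753 to 3581070), which ranked at 40.6% ± 9.004 from the top of the own lists. The next belonged to btd, a head and leg patterning gene (X from 9707848 to 9708186, intergenic, 13832 bp from the TSS), at 41.2% ± 12.9. They were followed by drm, a further gene of the odd-skipped family (2L from 3555717 to 3556013, intergenic, 16129 bp from the TSS), at 45.6% ± 5.39, and by exd, the homeodomain cofactor of Hox proteins (X from 15992223 to 15992646, promoter), at 58.1% ± 5.56 (all SD, n = 4). Of the 18 genes of this list that own a summit, 6 had a peak seen in all 4 own lists and 14 had a peak seen in at least 1.

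In the Wnt list, Apc, a scaffold of the complex that degrades beta-catenin (3R from 28844659 to 28845136), ranked at 14.9% ± 3.43 from the top of the own lists. The receptor gene fz3 (X from 769688 to 770136) ranked at 17.7% ± 2.87, pan, which encodes the fly TCF (4 from 69023 to 69500), at 18.8% ± 6.50, and the receptor gene fz4 (X from 7110149 to 7110516) at 41.3% ± 12.6 (all SD, n = 4, all at promoters). In the ribosomal list, RpL32 was followed by RpS7, RpL26 and RpS2, with mean ranks of 1.77% ± 1.00, 3.83% ± 0.975 and 4.70% ± 1.78. In the proteasome list, Rpn6 was followed by the core subunits Prosbeta2, at 1.60% ± 0.918, and Prosalpha7, at 5.17% ± 2.37, and by the base subunit Rpn2, at 6.999% ± 3.46 (all SD, n = 4). Of the genes that own a summit, 27 of 38 ribosomal and 18 of 23 proteasome genes had a peak seen in all 4 own lists.

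The other 13 lists did not pass. Hedgehog pathway genes had the highest ratio of all, 2.09 for 8 of 14 genes (2.60 ± 0.399 in the replicates, n = 4), with a raw permutation p of 0.0346 and an adjusted permutation p of 0.118. They passed in 7 of the alternatives, among them peaks seen in at least 2 own lists (ratio 2.86, adjusted permutation p = 0.0238), but the ratio was 1.30 with matching on a candidate peak at the promoter and 1.35 with gene bodies, with adjusted permutation p of 0.886 and 0.674. The co-receptor gene boi ranked at 16.5% ± 2.26 and the signal transducer smo at 26.9% ± 6.06. EGFR pathway genes had a ratio of 1.79 (10 of 20, adjusted permutation p = 0.160), with intronic peaks at ru and sty. Mesoderm markers had a ratio of 1.70 (9 of 19), with promoter peaks at tin and Mef2 in every replicate. Dpp pathway genes had a ratio of 1.55 (10 of 23), with tkv and Mad at promoters, and Notch pathway genes 1.26 (8 of 22), with Psn and mib1.

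Segmentation genes had a ratio of 1.46 in the conservative list (9 of 22, with kni and gsb-n each seen in 1 own list), but 0.563 ± 0.185 in the own lists (SD, n = 4). Ratios were 1.33 for tracheal and salivary genes (6 of 16, trh and kni), 1.30 for Hox and head selector genes (7 of 19, ey and ems; 0.954 ± 0.442 in the own lists), 1.27 for germline genes (4 of 11, tud and gcl) and 1.13 for endoderm and fat body genes (5 of 16, lab and ush; 0.725 ± 0.547 in the own lists). Ratios were below 1 for neural markers, at 0.8001 (4 of 18, loco and SoxN), for epidermis and cuticle genes, at 0.673 (4 of 21, rtv and grh), and for proneural and sensory organ genes, at 0.402 (2 of 18, scrt and Poxn). Adjusted permutation p of these lists and of the mesoderm, Dpp and Notch lists lay between 0.264 and 0.939.

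**Figure D4:**
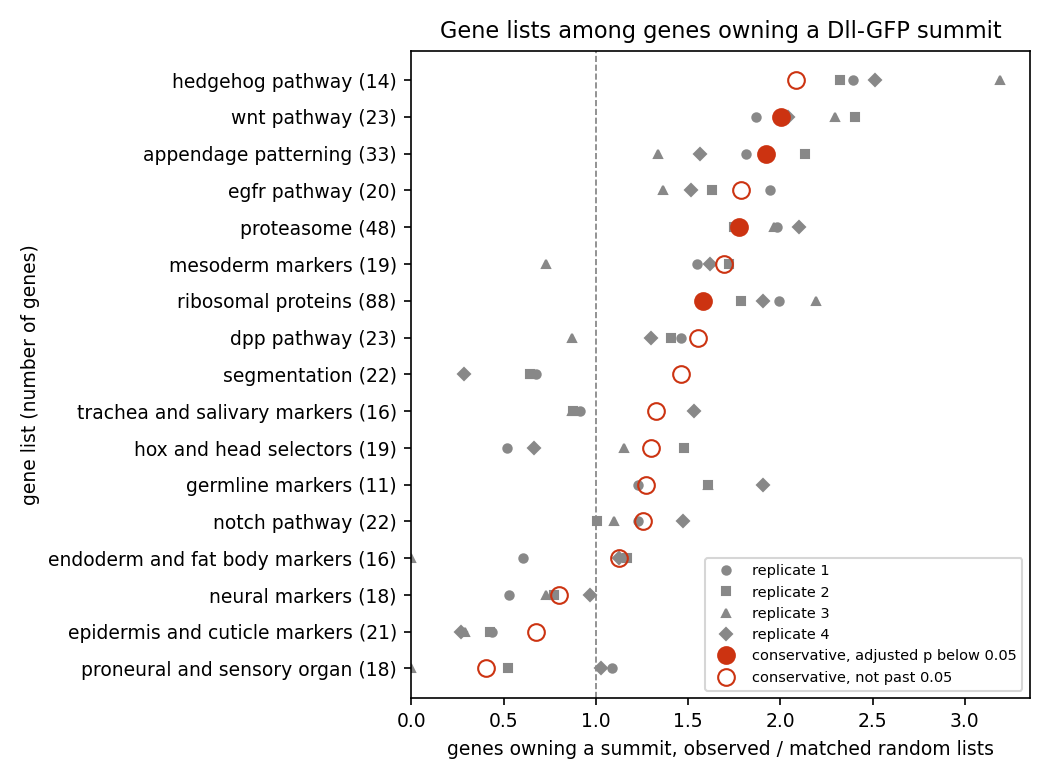
Ratio of list genes owning a summit to the mean of matched random lists, for 17 gene lists (size in brackets), in the conservative list (red circles, filled where the adjusted p is below 0.05) and in each replicate's own list (grey symbols). The dashed line marks a ratio of 1, and the appendage, Wnt, ribosomal and proteasome lists are filled.

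The last comparison asked which sequence motifs mark the summits, with the window reaching 50 bp to each side of the summit set against a window of the same size centred 400 bp to the left. The DREF motif TATCGATA, a mark of housekeeping promoters, was in 11.7% of summit windows and 0.711% of flanks. In the own lists it was in 17.0% ± 1.24 of summits against 0.727% ± 0.102 of flanks (SD, n = 4). CGATAT, bound by the insulator protein BEAF-32, was in 16.1% of summits against 4.02% of flanks, GAGAGAG, bound by GAGA factor, in 3.92% against 1.29%, and GGTCACAC, bound by M1BP, in 2.73% against 0.673%. A TATCGATA followed by T or preceded by A also counts as CGATAT, and hits shared by these words were not separated. Adjusted p from the exact McNemar test were 4.17e-137 for TATCGATA, 1.31e-95 for CGATAT, 4.81e-17 for GAGAGAG and 9.96e-16 for GGTCACAC, and each motif was more frequent at the summit in 4 of 4 replicates. For GAGAGAG the difference was 2.88 and 2.35 percentage points in replicates 1 and 2 but 0.951 and 0.624 in replicates 3 and 4, and among peaks seen in all 4 own lists its call ended, at 0.282 (adjusted exact McNemar p = 0.502).

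The homeodomain core motifs rose far less. TAATTA was in 7.23% of summits against 5.80% of flanks (adjusted exact McNemar p = 0.0110; a difference of 1.65 ± 0.982 percentage points in the own lists), and TAATTG in 9.13% against 7.63% (adjusted exact McNemar p = 0.0172; 1.36 ± 0.638, both SD, n = 4). Among peaks seen in all 4 own lists TAATTA passed and TAATTG did not (adjusted exact McNemar p = 0.00268 and 0.0803). With windows of 100 bp to each side TAATTG passed and TAATTA did not (adjusted exact McNemar p = 0.00292 and 0.0601). TAATGA, a further homeodomain word, was in 4.54% against 4.88%, TTTATKG of posterior Hox proteins and Caudal in 5.36% against 5.11%, TGACAG of Homothorax in 3.34% against 2.90% and TGATTWAT of Extradenticle with Hox in 1.19% against 1.23%, and none of these passed against the left flank. TGACAG passed against the right flank, at 0.980 percentage points (adjusted exact McNemar p = 0.00736). TAATTA was in 11.8% ± 1.23 of summits in bin 1 of the own lists by signal and in 5.84% ± 1.88 in bin 5 (SD, n = 4). Summit windows in bin 1 of the conservative list had a GC content of 35.5%, against 45.5% in their flanks. Over all conservative summits it was 40.6% against 42.9%. The order was reversed in bin 5, at 43.6% against 41.7%, and at summits over 1000 bp from a TSS, at 43.4% against 40.2%. Set against summit windows shuffled with their dinucleotide counts kept, the difference was -0.423 percentage points for TAATTA and -1.13 for TAATTG. Neither passed, with adjusted exact McNemar p of 0.452 and 0.103. TAATGA (-3.71) and TGATTWAT (-0.673) passed as lower than in the shuffle, but not as lower than in the left flank (adjusted exact McNemar p = 0.549 and 0.947).

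At the 605 summits over 1000 bp from any protein-coding TSS, TAATTA was as frequent at the summit as in the flank, at 6.12% in both. There GAGAGAG, with 8.93% of summits (adjusted exact McNemar p = 3.20e-06), and TATCGATA, with 4.79% against 0.165% (adjusted exact McNemar p = 1.33e-06), were the 2 motifs that passed. Over all summits, 5 motifs were less frequent than in the flanks, namely CCGGAA of ETS factors (2.36% against 3.81%), CACCTG of E-box proteins (3.27% against 4.61%), CACACACA (2.06% against 2.98%), GGAATG of Scalloped (3.27% against 4.21%) and GGGCGG of Sp factors (2.83% against 3.67%). Their adjusted exact McNemar p lay between 0.000115 and 0.0358. None of these 5 passed as lower against the same shuffle: the difference was 0 percentage points for CCGGAA, -0.538 for GGAATG and 0.519 for CACCTG, and CACACACA (1.499) and GGGCGG (0.769) passed as higher. The remaining 8 of the 23 motifs, for Zelda, Grainyhead, GATA factors, CATATG E-box proteins, TCF, Mad, Su(H) and Tinman, did not pass against the left flank.

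**Figure D5:**
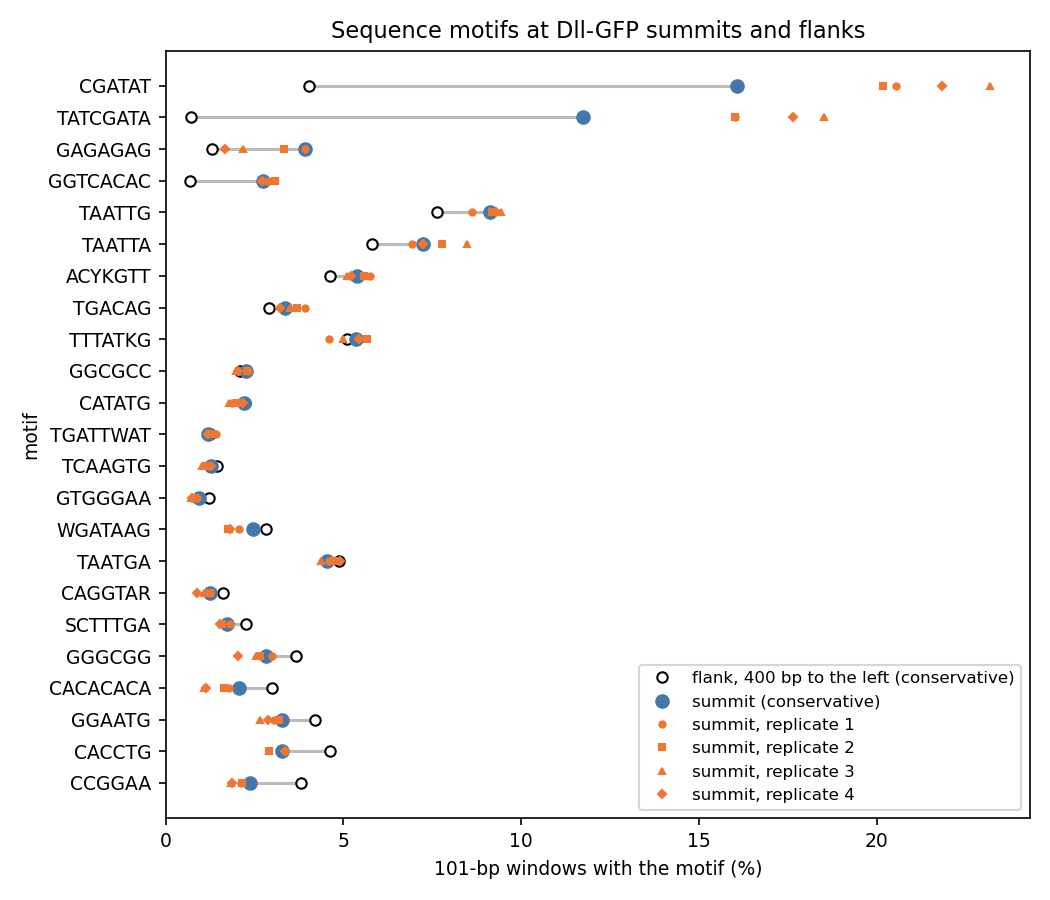
Share of windows of 50 bp to each side (%) with each of 23 motifs at conservative summits (blue), in flanks 400 bp to the left (open circles) and at the summits of each replicate's own list (orange). TATCGATA is in 11.7% of conservative summits and 0.711% of flanks, while TAATTA is in 7.23% and 5.80%.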

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

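Peaks on the mitochondrial genome, which no comparison used, numbered 8 in replicate 1 and 7 in replicate 2. These peaks stood out because, by a fixed rule for independent counts, a count of 0 allows only 3. They held the highest signal of those own lists, up to 5918 in replicate 1 and 8106 in replicate 2. Replicates 3 and 4 had 0 mitochondrial peaks in their thresholded lists and 0 among their 44491 and 39776 ranked candidates, while replicates 1 and 2 had 43911 and 39030 ranked candidates. Whether peaks on 1 genome are independent counts, and whether mitochondrial reads were handled alike in the 4 replicates, was not tested. The conservative list held 6 mitochondrial peaks, with signal up to 22402. Of the other thresholded series-level lists, only that of 6226 peaks held any.

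Among 50 sets of 4 replicate values, 2 had a replicate far from the others, and chance alone sets apart about 1 in 20. The ratio of segmentation genes owning a summit was 0.286 in replicate 4 and between 0.644 and 0.676 in the others, with 1 to 3 genes of 22 behind each value. For tracheal and salivary genes the ratio was 1.53 in replicate 4 and between 0.871 and 0.916 in the others, with 2 to 4 genes of 16.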

How the results depend on the processing

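The promoter excess and the TATCGATA excess passed under every alternative run for them, from 4.34-fold to 12.5-fold and from 4.63 to 20.5 percentage points; keeping 1 summit per merged region was chosen after seeing the data, and the causes of the changes below were not tested. Settings without 1 replicate kept only peaks seen in at least 2 of the 3 remaining own lists, except in values per replicate and the share seen in every replicate, so they also ask for more support than the conservative list does. The peaks they kept, with their summits and signal, still come from the conservative list, which derives from all 4 replicates. These settings therefore do not show independence from the replicate left out. The share of a replicate's peaks seen in another moved to 65.9% with a reciprocal overlap of 50% and 69.7% with summits within 100 bp. The share of series-level peaks seen in every replicate was 76.5% for the upper 50% by signal, 40.9%, 51.8%, 53.9%, 56.1%, 57.4% and 61.4% for the series-level lists of 6226, 4781, 4640, 4347, 4318 and 4009 peaks, 45.2% with merged regions, 21.7% with reciprocal overlap, 33.4% with summits within 100 bp, and 48.7% to 53.7% without 1 replicate. The number of peaks was 2601 in the upper 50%, 2480 seen in all 4 replicates, and 3192 to 3544 without 1 replicate, fewer by construction. Mean rho was 0.819 for the upper 50% and 0.922 with merged regions. The 5' UTR excess turned to 0.504-fold with the wider promoter and no longer passed in the upper 50% (1.05-fold). Other exons newly passed as under-represented in 9 settings, at 0.403-fold in the upper 50% and 0.124-fold with peaks in all 4 replicates. The number of lists that passed was 2 with the upper 50%, 2 with the list of 6226 peaks, 2 with peaks in all 4 replicates, 2 with gene bodies plus 2000 bp upstream, 0 with summits over 1000 bp from a TSS, 0 with matching on a candidate at the promoter, and 2 to 3 without 1 replicate, where peaks in at least 2 of all 4 replicates already gave 3. The appendage ratio no longer passed with the upper 50% (2.13), the list of 4318 peaks (1.87), peaks in at least 2 replicates (1.89) or in all 4 (1.76), without 1 replicate (1.41 to 1.93), distal summits (1.55), the candidate matching (1.26) or gene bodies (1.06). The Wnt ratio no longer passed with the upper 50% (1.89), the lists of 6226 (1.79) and 4640 peaks (1.92), peaks in at least 2 (2.03) or all 4 replicates (2.10), without 1 replicate (2.08 to 2.33), distal summits (2.07), the candidate matching (1.39) or gene bodies (1.34). The ribosomal ratio no longer passed with distal summits (1.35) or candidate matching (1.19); the proteasome ratio no longer passed with the lists of 6226 (1.45) and 4347 peaks (1.71), merged regions (1.69) or candidate matching (1.57), and was 0 with distal summits. The Hedgehog ratio newly passed in 7 settings: the lists of 4781 (2.84), 4347 (2.76), 4318 (2.503) and 4009 peaks (3.02), peaks in at least 2 replicates (2.86), and without replicate 2 (3.25) or 4 (3.01); it was 1.30 with candidate matching and 1.35 with gene bodies. Of the motifs, 2 were higher and 0 lower at distal summits, and 3 were lower with the lists of 4781, 4640 and 4009 peaks. With the shuffle 3 others were lower, namely TAATGA (-3.71), TGATTWAT (-0.673) and the TCF motif (-0.942), and none of the 5 reported as lower. TAATTA no longer passed with windows of 100 bp (1.42 points) or at distal summits (0 points), and turned to -0.423 with the shuffle. TAATTG no longer passed with the lists of 4781 (1.02), 4640 (1.29), 4318 (1.09) and 4009 peaks (1.07) or peaks in all 4 replicates (1.77), nor without replicate 1 or 2, in a range from 1.47 to 1.86 without 1 replicate, and turned to -1.13 with the shuffle and -0.992 at distal summits. With the shuffle, CACACACA turned to 1.499, CACCTG to 0.519 and GGGCGG to 0.769; at distal summits CACACACA turned to 1.98 and GGGCGG to 0.331. GAGAGAG no longer passed with peaks in all 4 replicates (0.282), CCGGAA with the shuffle (0) or at distal summits, and GGAATG in 11 settings. TGACAG newly passed with the right flank (0.980), windows of 100 bp (1.65) and the list of 6226 peaks (0.772), the Grainyhead motif with the right flank (1.36) and the shuffle (1.21), and the Mad motif with the shuffle (0.730). As lower, the TCF motif also newly passed with the list of 6226 peaks (-0.579) and CATATG with the right flank (-0.692). Of 1811 alternative values, 75 that passed in neither setting changed sign. Of the 65 named genes, 9 owned no peak when all 4 replicates were required, and 317 of their 865 ranks moved by more than the replicate spread. That spread was taken as 0 for genes without an SD, so any change in them counted as moved. Ranks are shares of a list, so a smaller set of peaks also moves them by construction. Of 342 list values and 450 motif values, 297 and 395 kept their call or, not passing in either setting, stayed uncalled whatever their sign, or, for the numbers of lists and motifs, stayed within 1.5 times, and 7 and 11 newly passed.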

Other observations

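Transfer RNA genes stood near more summits than the shifts gave. Of the conservative summits, 90 lay within 500 bp of 1 of 290 tRNA genes, against a mean of 9.73 and a highest value of 18 in 100 circular shifts, and 56 of these were over 1000 bp from any protein-coding TSS. The own lists held 58 ± 17.6 summits within 500 bp of a tRNA gene (SD, n = 4). This count was chosen after the data were seen.

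Of the tests below, that of TAATTA at distal summits was written after its result was seen, and the adjusted p for weak peaks was taken in place of the raw p after both were seen. No biological explanation was tested against a second group, because the design has 1. TATCGATA was in 14.5% of the promoter summits. Promoters without a peak, taken at the same offsets from the TSS, held it in 1.13% on average and at most 1.51% in 100 draws, which argues against a property of promoters in general, though these may include promoters that are inactive in embryos. Shuffled promoter summit windows held it in 0.259% on average and at most 0.385%, which argues against base composition. Whether Dll-GFP itself, or chromatin of active promoters in any immunoprecipitation, gave these peaks is left open, since no control library was analysed here.

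For TAATTA, 20 shuffles of the summit windows held it in 7.72% on average, from 7.03% to 8.42%, and the observed 7.23% lay within that range. The base composition of the summit windows thus gave TAATTA about as often as observed. Flank windows were not shuffled, so this does not decide whether low GC content accounts for the excess over the flanks. Binding of homeodomain sites away from protein-coding promoters was left open. The summit minus flank difference at distal summits was 0 points, with a bootstrap 95% interval from -2.64 to 2.81, which includes the 1.42 points seen over all summits.

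Whether the excess of appendage genes reflects peaks at any accessible promoter could not be decided. With random genes matched also on a ranked candidate peak at the promoter, the ratio went from 1.92 to 1.26, with a permutation p of 0.234. The ranked candidates include every conservative peak, so this matching is made in part on the tested peaks themselves, and accessibility was not measured. The candidates also come from the same immunoprecipitations, so the matching may remove weak Dll binding. Weak peaks near the threshold stay open. Among the upper 50% of peaks by signal the ratio was 2.13 with a raw permutation p of 0.0290, which met the bound set in advance, but that bound took no account of the 17 lists, and the adjusted permutation p was 0.150. With peaks in all 4 replicates the ratio was 1.76 (adjusted permutation p = 0.553), and 14 of the 18 genes had a peak seen in at least 1 own list.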
